A study of Mus musculus with 437 samples.

How the data were processed

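The series holds 437 samples of 21 inbred strains, 1 more than its title states, and 7 brain regions, and 436 of them came with a scanner file. Per the labels, total RNA was extracted with TRIzol and cleaned on Qiagen RNeasy columns, and 15 µg were labelled with the Agilent Direct Label kit, brain RNA with Cy3 and the Stratagene universal mouse reference RNA with Cy5, without a dye swap. By the design text every array holds a separate pool of 3 animals. Sex, age and the pooling of regions from the same animals are not given in the sources used here. Per the file headers, the authors extracted the intensity of each spot with Agilent Feature Extraction 8.5.1.1 (428 arrays), A.7.5.1 (7 arrays) and 8.1.1.1 (1 array), and the values are intensities of each channel with their local backgrounds. The deposited value table holds log2 ratios of Cy5 over Cy3, which is reference over brain, with array medians near 0 (median 0.037, from −0.035 to 0.16). Its columns correlated with the own array at a median of 0.992 (lowest 0.849) with a slope of 0.79 against the scanner software's processed ratio, and its exact normalization remains unknown. It was used as an alternative after its sign had been turned.

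The mean signals were corrected for background with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, and the log2 ratio of Cy3 over Cy5 was averaged over the spots of a probe. Spots with an outlier flag in either channel were left out, a median of 20% of the spots of an array (0.314% to 83.7%) and 22.2% of all probe values. The fits therefore ran on each probe's own values, with compiled code (Rcpp 1.1.0, and version 1.17.8 of data.table) for designs with missing values, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15. A probe was kept if it was well above background in Cy3 on at least 50% of the arrays of at least 1 region or 1 strain, which left 20694 of 20868 probes from 21318 spots. The median array had 95.7% of spots well above background in Cy3 and 96.5% in Cy5. The signal over background of the dimmest arrays limits the precision of their weak probes. Arrays of a group correlated at a median of 0.927, the closest pair at 0.9905, and 0 arrays were identical.

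No reference genome was given. Probes were named by their transcript accession through a RefSeq list of the mouse assembly GRCm38.p6, used for names alone (14227 probes), or by the description in the file (769), and 5872 stayed without a gene name. The build of the coordinates in the files is not given in the sources used here, so no coordinates were used. In all 14591 genes were named, 358 of them by more than 1 probe, and each gene was taken by its probe with the highest mean Cy3 signal.

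The comparisons, the 27 gene lists and most of the alternatives were fixed before the data were examined. Regions were compared in 1 limma fit of the means per strain and region, with strain as a block and strains as replicates, each region against the mean of the others and cingulate against frontal cortex. Strains were compared within each region by an F test over arrays. Each strain was set against the mean of the others over regions, wild-derived against classical strains by strain means, and DBA/2J against C57BL/6J in each region. The interaction of strain and region was tested by F. Strain contrasts needed values in at least 4 regions. A call took a Benjamini-Hochberg adjusted p under 0.05 and a 2-fold difference, and the F tests took the adjusted p alone. The wild-derived class is textbook knowledge and is not a label. Named genes followed a fixed rule. In each region these were the 3 largest rises and the largest fall, between the 2 cortices and between the strain classes the 5 largest each way, and in each strain the largest each way. For the interaction they were the 5 largest F. Clone and predicted names were counted and not ranked. Some genes that the rule selects are not reported here. For DBA/2J against C57BL/6J the rule asked for genes called the same way in every region, which left no named gene.

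The lists were cerebellar granule cell, Purkinje cell, striatal projection neuron, hippocampal neuron, olfactory bulb neuron, olfactory sensory axon, amygdala neuron, neocortical projection neuron, thalamic neuron, hypothalamic neuropeptide neuron, GABAergic interneuron, oligodendrocyte and myelin, astrocyte, microglia, endothelial cell, choroid plexus, blood cell, immediate early genes, GABA-A receptor subunits, ionotropic glutamate receptor subunits, monoamine receptors, neuropeptides, antigen presentation, interferon-stimulated genes, glutathione transferases, known strain-variant genes and sex-linked genes. Some genes sit on more than 1 list, such as Neurod6, Wfs1, Calb2 and Pvalb. Camera ran over 14347 genes with a preset correlation of 0.01 between genes and again with the correlation estimated, with adjustment over all lists and comparisons of a family.

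Alternatives were the scanner software's processed signals, the deposited ratios, median centring, Aquantile, other filters, other units of the fit, array weights, scan day as a block, fewer strains and leaving out replicates. Added after seeing the data were fits with the spots of an outlier flag, the Cy3 channel alone, fits without 5 doubted arrays, the periods before and after the longest gap of 133 days between scan days, scan day as a block for regions, means per strain and scan day, and the strain classes without PERA/EiJ. Arrays were doubted if they matched the profile of another region best (2000 probes, 4 arrays) or correlated with their group under 0.5 (1 array). Of 68 scan days 43 held 1 strain, and 10 strains lay wholly before and 10 wholly after the gap, with C3H/HeJ on both sides.

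Each comparison was tested on simulated data in which 200 of 20694 probes were changed. The simulated noise was independent between probes and arrays, with no effect of strain, region or scan day outside the changed probes. The numbers of false calls given here therefore need not hold for the real arrays. At 4-fold and 2.5-fold the region test recovered 100% and 100%, cingulate against frontal cortex 100% and 100%, each strain 97% and 97.5%, the strain classes 100% and 100%, DBA/2J against C57BL/6J 74.5% and 52.5%, strains within a region 73.5% and 37.5%, and the interaction 69.5% and 27%. False calls were 0 for the first 4, then 6 and 4, 8 and 5, and 9 and 3. Camera called 20 of 20 raised lists and 1 of 20 unchanged lists. Chance was tested by drawing 100 splits of the samples for each count, 40 for the lists by region, and correlations were tested with 1e+05 permutations.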

Results

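RNA from 7 brain regions of 21 inbred mouse strains was measured on Agilent oligonucleotide arrays with 2 colours. The regions were amygdala, basal ganglia, cerebellum, cingulate cortex, frontal cortex, hippocampus and olfactory bulb. Brain RNA carried Cy3 and a universal mouse reference RNA, by its label the same on every array, carried Cy5, so each value is a log2 ratio of brain over reference. By textbook knowledge of their origin, 16 of the strains are classical laboratory strains. The other 5, CAST/Ei, MOLF/Ei, PERA/EiJ, PWD and SPRET/Ei, derive from wild mice, and SPRET/Ei belongs to another species, Mus spretus. Tissue of 3 animals was pooled for each array. The 437 samples fell into 147 groups of 1 strain and 1 region, 134 of which held 3 samples, with 1 in the smallest and 4 in the largest. Of the samples 436 had a scanner file, and the sample without one was from olfactory bulb of NZB/B1NJ. A median of 95.7% of the spots were well above background in the Cy3 channel (66.2% to 99.1% over the arrays), and the median Cy3 signal of an array ranged from 368 to 2450. The number of arrays limited the precision, and 22.2% of the probe values were left out because the scanner software had given their spots an outlier flag.

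The largest differences between regions included genes of neurons and of choroid plexus. Rgs9, a regulator of dopamine receptor signalling, was 25-fold higher in basal ganglia than in the mean of the other regions, and S100a5, a calcium-binding protein of olfactory sensory neurons, was 31.7-fold higher in olfactory bulb. Gabra6, the GABA-A receptor subunit of cerebellar granule cells, was 27.2-fold higher in cerebellum. Ttr, the thyroid hormone carrier made by choroid plexus, led the hippocampus with a 12.7-fold rise. Each region was set against the mean of the other regions with limma, strain means as replicates and strain as a block, to ask which genes mark a region whatever the strain. A large rise of a gene in 1 region therefore lowers its values in the other regions. A call needed an adjusted p under 0.05 and a fold of at least 2, and 1223 of 20694 probes were called in at least 1 region. Cerebellum gave 838 calls (236 higher, 602 lower), basal ganglia 260 (186 and 74), olfactory bulb 187 (117 and 70), hippocampus 182 (151 and 31), amygdala 106 (90 and 16), frontal cortex 89 (70 and 19) and cingulate cortex 53 (33 and 20). With scan day as a block 1252 probes were called, within the arrays scanned before the longest gap between scan days 1309, and within those after it 1256.

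**Figure D1:**
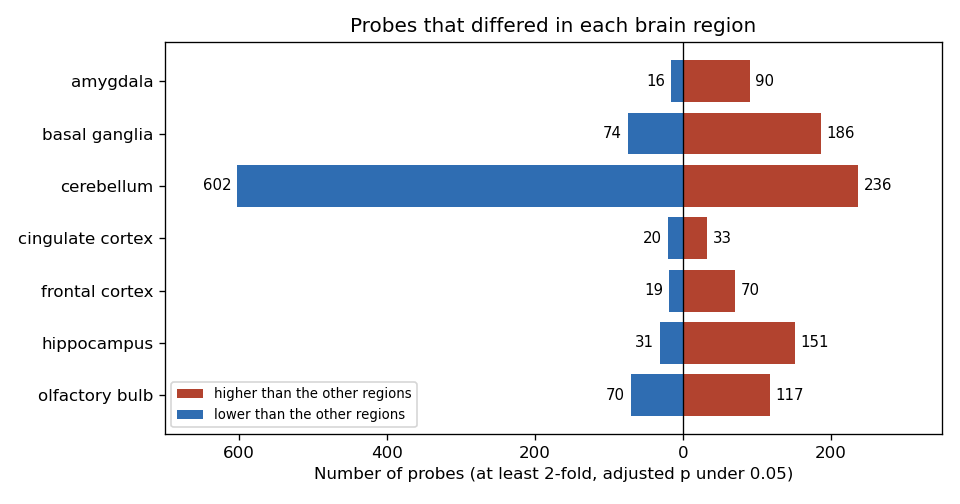
Number of probes called in each region against the mean of the other regions, with bars to the right for higher and to the left for lower probes (limma, adjusted p under 0.05 and at least 2-fold). Cerebellum holds 838 of the calls, of which 602 are lower, while each of the other regions has more higher than lower calls.

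In cerebellum the granule cell and Purkinje cell genes rose together. Gabra6 was higher by 4.77 ± 0.10 (log2 ± SE) in 17 of the 17 strains with a value, and Pcp2, a Purkinje cell protein, by 4.19 ± 0.11 in 21 of 21 (limma adjusted p = 8.5e-68 and 1.1e-63). En2, a homeobox factor that patterns midbrain and hindbrain, rose by 3.13 ± 0.09 in 20 of 21 strains (adjusted p = 1.9e-62). Of 8 granule cell genes 6 rose, among them Cbln3 (2.64 ± 0.07), Zic1 (2.44 ± 0.12) and Cdh15 (2.15 ± 0.10), and the number was also 6 adjusted over the list alone. Slc17a7, a vesicular glutamate transporter on that list, had a difference of −0.79 ± 0.20 that did not reach the fold. Of 10 Purkinje cell genes 8 rose (8 adjusted over the list alone), with Pvalb at 2.39 ± 0.06, Slc1a6 at 2.15 ± 0.07 and Itpr1 at 1.86 ± 0.09. Camera, limma's test of a list against all other genes, gave the granule cell list adjusted p = 6.5e-10 (adjusted p = 1.1e-05 with an estimated correlation) and the Purkinje cell list 4.5e-12 (adjusted p = 1.1e-05 with an estimated correlation).

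Several neuropeptide and microglial genes were low in cerebellum. Sst (−3.94 ± 0.12), Vip (−3.27 ± 0.11), Tac1 (−2.84 ± 0.16) and Cck (−2.77 ± 0.14), all precursors of neuropeptides, were among 8 of 15 neuropeptide genes that fell (8 adjusted over the list alone; adjusted p = 3.2e-09, adjusted p = 0.0052 with an estimated correlation). The immediate early genes Egr1 (−2.87 ± 0.12) and Arc (−2.58 ± 0.10), which neuronal activity induces, were among 6 of 14 that fell, with adjusted p = 0.0017 for the list and adjusted p = 0.11 with an estimated correlation. Among microglial genes P2ry12 (−1.70 ± 0.09), a purine receptor, was among the 5 that fell out of 13 (adjusted p = 6.5e-07, adjusted p = 0.0043 with an estimated correlation). Of 11 genes of GABAergic interneurons 5 fell and Pvalb, which is also on the Purkinje cell list, rose (adjusted p = 0.015 for the list, adjusted p = 0.12 with an estimated correlation). Thalamic neuron genes were higher as a list, with Calb2 (2.55 ± 0.12), Rora (1.77 ± 0.07) and Prkcd (1.61 ± 0.08) called out of 7 (adjusted p = 0.0028, adjusted p = 0.0054 with an estimated correlation). Rora is also on the Purkinje cell list, Calb2 on the olfactory bulb neuron list and Prkcd on the amygdala neuron list. The counts adjusted over the list alone were 6 immediate early, 5 microglial, 6 interneuron and 3 thalamic neuron genes.

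Basal ganglia carried the genes of striatal projection neurons, the inhibitory output cells of the striatum. Rgs9 rose by 4.65 ± 0.10 in 20 of 20 strains (limma adjusted p = 1.4e-72), and Tac1, the substance P precursor, by 3.96 ± 0.16 in 19 of 19 (6.4e-47). Rarb (3.41 ± 0.07), Penk (3.34 ± 0.14), the enkephalin precursor, and the dopamine receptor Drd2 (3.02 ± 0.05) followed, and 9 of the 12 genes of the list rose (9 adjusted over the list alone). The spot of Penk was saturated in Cy3 on 16 of 237 arrays outside hippocampus, so its difference may be understated. Pdyn (0.94 ± 0.10) and Isl1 (0.60 ± 0.03) did not reach the fold. The list was higher with adjusted p = 6.9e-47 in camera and adjusted p = 9.2e-13 with an estimated correlation. Ptgds, a prostaglandin synthase of meninges and choroid plexus, was lower by a log2 difference of −2.85 ± 0.12 in 20 of 20 strains (adjusted p = 5.5e-45). The spot was saturated in Cy3 on 45 of 264 arrays of the other regions.

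In olfactory bulb, genes of bulb neurons and of the incoming sensory axons were high. S100a5 rose by 4.99 ± 0.10 in 21 of 21 strains (limma adjusted p = 7.5e-82). Cdhr1, a cadherin of mitral and tufted cells, rose by 4.6 ± 0.13 in 21 of 21 (1.8e-63), and Dlx1, a homeobox factor of interneurons, by 3.56 ± 0.14 in 17 of 17 (5.3e-42). Th, the enzyme that starts dopamine synthesis, rose by 2.80 ± 0.06 and Dlx2 by 2.78 ± 0.08, and 8 of 11 bulb neuron genes rose (8 adjusted over the list alone; adjusted p = 3.6e-34, adjusted p = 2.6e-14 with an estimated correlation). Of 7 sensory axon genes 2 rose, S100a5 and Stoml3 (1.12 ± 0.04), while Omp, the marker protein of mature sensory neurons, stood at 0.98 ± 0.05 (2 adjusted over the list alone; adjusted p = 2.9e-06, adjusted p = 0.00021 with an estimated correlation). Calb1, a calcium buffer, was lower in 20 of 20 strains at −2.62 ± 0.14 (adjusted p = 5.3e-34). None of 14 interferon-stimulated genes reached the fold, Ifitm3 (0.60 ± 0.10) and Ifit2 (0.59 ± 0.06) being the furthest from 0, yet camera placed the list higher in olfactory bulb (adjusted p = 0.00028, adjusted p = 0.043 with an estimated correlation).

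The hippocampus joined genes of its pyramidal neurons with those of choroid plexus, the epithelium that secretes cerebrospinal fluid. Ttr rose by 3.66 ± 0.17 in 16 of 16 strains (limma adjusted p = 1.3e-36). Spink8, a protease inhibitor, rose by 2.83 ± 0.10 in 21 of 21 (2.3e-53), and Crym, a thyroid hormone binding protein, by 2.56 ± 0.23 in 17 of 17 (2e-18). Penk was lower, at −1.68 ± 0.14 in 20 of 20 strains (1.6e-19), with its spot saturated in Cy3 on 16 of 237 arrays of the other regions. Fibcd1 (2.19 ± 0.09), Neurod6 (1.87 ± 0.12) and Wfs1 (1.23 ± 0.07) rose with Spink8 among 10 hippocampal neuron genes (4 adjusted over the list alone; adjusted p = 1e-09, adjusted p = 1.2e-06 with an estimated correlation). Of 11 choroid plexus genes 7 rose (7 adjusted over the list alone), with Sostdc1 at 2.28 ± 0.11, Folr1 at 1.89 ± 0.08 and Aqp1 at 1.33 ± 0.15 (adjusted p = 2.1e-06, adjusted p = 0.0031 with an estimated correlation). Ttr also rose in cerebellum, by 2.26 ± 0.16. Of 11 amygdala neuron genes 5 rose in hippocampus too, Wfs1 among them (median 0.94; adjusted p = 0.0075, adjusted p = 0.09 with an estimated correlation), against a median of 0.91 in amygdala itself. The size of the Ttr difference varied between strains from 1.35 to 5.76 (mean 3.63, SD 1.11, n = 16), against 1.39 to 2.72 for Vip in frontal cortex (mean 1.9, SD 0.38, n = 20). Each strain was set against those of its other regions that had a value, so missing values can add to this spread.

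**Figure D2:**
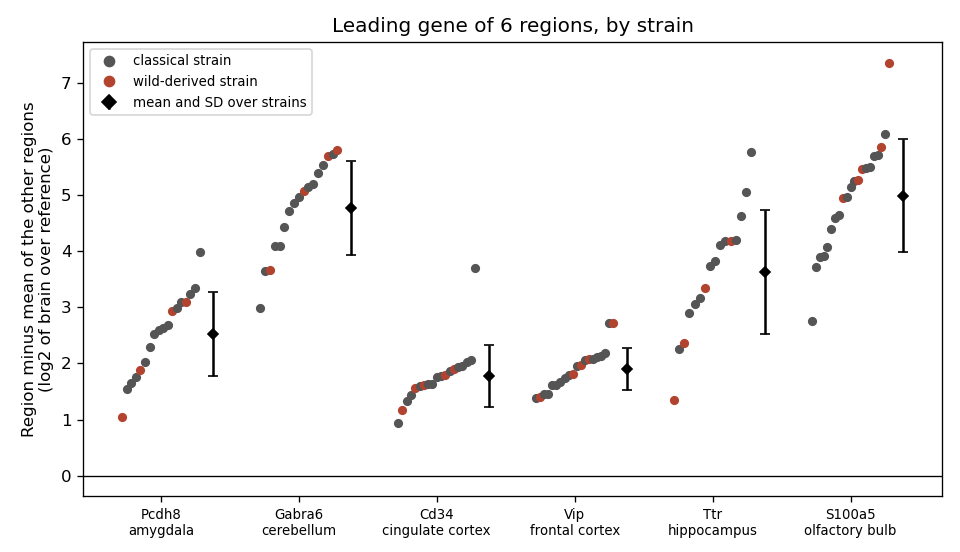
Log2 difference of the leading gene of 6 regions from the mean of the other regions, 1 point per strain (grey classical, red wild-derived) with the mean and SD beside them (log2 scale, 16 to 21 strains with a value). Vip in frontal cortex lies between 1.39 and 2.72 in 20 strains, while Ttr in hippocampus spreads from 1.35 to 5.76, and every point of the 6 genes is above 0.

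Several neuropeptide genes were higher in amygdala. Npy2r, a receptor of neuropeptide Y, rose by 2.48 ± 0.11 in 20 of 20 strains (limma adjusted p = 2.2e-40). Pcdh8, a protocadherin, rose by 2.5 ± 0.14 in 18 of 18 (1.7e-30), and Bhlhe22, a transcription factor of neurons, by 2.31 ± 0.26 in 12 of 12 (4.5e-11). Nts (2.23 ± 0.09), the neurotensin precursor, Lypd1 (1.94 ± 0.08), Lmo3 (1.77 ± 0.11) and Cartpt (1.62 ± 0.12) led the 5 of 11 amygdala neuron genes that rose (5 adjusted over the list alone; adjusted p = 3.1e-13, adjusted p = 2.3e-06 with an estimated correlation). Neuropeptide genes rose in 8 of 15 cases, with Sst at 1.64 ± 0.12 and Gal, the galanin precursor, at 1.49 ± 0.17 (8 adjusted over the list alone; adjusted p = 1e-14, adjusted p = 0.00021 with an estimated correlation). Genes of hypothalamic peptide neurons, which lie beside the amygdala, rose in 2 of 10 cases, Gal and Trh (1.12 ± 0.10), with adjusted p = 2e-05 for the list and adjusted p = 0.0014 with an estimated correlation (2 adjusted over the list alone). Itpr1, the calcium release channel, was lower at −1.53 ± 0.09 in 19 of 19 strains (adjusted p = 1.7e-29), with its spot saturated in Cy3 on 6 of 229 arrays of the other regions. Myelin genes were lower as a list without a called gene (median −0.52; adjusted p = 6.5e-07, adjusted p = 0.028 with an estimated correlation). No blood cell gene was called, S100a8 standing at −0.92 ± 0.13 (adjusted p = 0.0034 for the list of 8, adjusted p = 0.12 with an estimated correlation).

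Genes of neocortical projection neurons were higher in frontal and in cingulate cortex. Epop, a protein of chromatin-modifying complexes, rose in frontal cortex by 1.88 ± 0.07 in 20 of 20 strains and in cingulate cortex by 1.53 ± 0.07 in 21 of 21 (limma adjusted p = 3e-46 and 9.5e-39). Vip, a peptide of cortical interneurons, rose in frontal cortex by 1.90 ± 0.11 in 20 of 20 strains (6.5e-32) and Stx1a, a syntaxin of transmitter release, by 1.76 ± 0.08 in 17 of 17 (5.7e-37). Cd34, a glycoprotein of blood vessel and blood precursor cells, rose in cingulate cortex by 1.71 ± 0.09 in 19 of 19 strains (5.6e-35) and Robo3, an axon guidance receptor, by 1.54 ± 0.10 in 21 of 21 (1.6e-27). Mef2c (1.57 ± 0.08), a transcription factor of cortical neurons, was among 6 of 12 neocortical genes that rose in frontal cortex (6 adjusted over the list alone; adjusted p = 2.1e-16, adjusted p = 6.3e-07 with an estimated correlation). In cingulate cortex 5 of the 12 rose, each of which also rose in frontal cortex, with Fezf2 (1.36 ± 0.10) the furthest (5 adjusted over the list alone; adjusted p = 5.2e-12, adjusted p = 1.6e-05 with an estimated correlation). Egr1 (1.33 ± 0.12) and Arc (1.31 ± 0.10) were the 2 of 14 immediate early genes that rose in cingulate cortex (2 adjusted over the list alone; adjusted p = 1.2e-10, adjusted p = 0.00061 with an estimated correlation). Nts was lower in frontal cortex at −1.73 ± 0.09 in 21 of 21 strains (4.5e-34), and Calb2, calretinin, in cingulate cortex at −1.87 ± 0.11 in 21 of 21 (2e-30).

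Cingulate cortex differed from frontal cortex above all in myelin. Cldn11, the tight junction protein of myelin, was higher in cingulate cortex by 1.73 ± 0.15 in 21 of 21 strains (limma adjusted p = 9.6e-18). Fa2h, which makes the hydroxylated lipids of myelin, was higher by 1.61 ± 0.14 in 21 of 21 (1.7e-17), and Mog, a surface protein of the sheath, by 1.56 ± 0.12 in 17 of 17 (7.1e-20). Mal (1.66 ± 0.20, 11 of 12 strains, 3.2e-10) and Tspan2 (1.65 ± 0.17, 19 of 19, 2.4e-13), both membrane proteins of oligodendrocytes, completed the 5 largest rises. Of 12 myelin and oligodendrocyte genes 8 rose (8 adjusted over the list alone), the median of the list was 1.1, and camera gave adjusted p = 2.5e-38 (adjusted p = 6.4e-09 with an estimated correlation). The list's median was higher in cingulate cortex in 21 of 21 strains, by 0.39 to 1.85 (mean 1.15, SD 0.36). Against all other regions the list fell in frontal cortex, with 5 of 12 genes called and Mbp, the myelin basic protein, at −1.14 ± 0.13 (5 adjusted over the list alone; adjusted p = 8.5e-16, adjusted p = 0.00027 with an estimated correlation).

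Genes that favoured frontal over cingulate cortex were fewer. Frzb, a secreted inhibitor of Wnt signalling, differed by −1.29 ± 0.12 (lower in cingulate cortex in 19 of 20 strains, limma adjusted p = 6.1e-16) and Wfs1, a protein of the endoplasmic reticulum, by −1.09 ± 0.08 (20 of 20, 1.7e-21). Calb1 (−1.08 ± 0.18, 20 of 20, 3.1e-06) and Cpne4, a copine (−1.06 ± 0.16, 18 of 20, 6e-08) were also called, Cpne4 at −0.74 and below the fold in the Cy3 channel alone. Bhlhe22 (−1.08 ± 0.34, 6 of 7, 0.032) had values in few strains, and its call ended under several alternatives. In all 28 probes were higher and 9 lower, 37 together, 35 with scan day as a block, 45 within the arrays before the scan gap and 34 after it. Beside myelin, camera called the amygdala neuron list lower (1 of 11 genes called, 1 adjusted over the list alone; adjusted p = 0.00046, adjusted p = 0.032 with an estimated correlation). It called the thalamic neuron list higher (0 of 7; adjusted p = 0.008, adjusted p = 0.022 with an estimated correlation). Those 3 of 9 called lists held with an estimated correlation. The other 6 were GABA-A receptor subunits, immediate early genes, glutathione transferases, striatal projection neurons, neocortical projection neurons and glutamate receptor subunits, with adjusted p from 0.052 to 0.20 with an estimated correlation.

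Over all regions 76 of 189 tests of 27 lists passed the threshold in camera, 29 of them upward, and 43 also passed with an estimated correlation. Thalamic neuron genes were lower in frontal cortex, with Calb2 the called gene at −1.57 ± 0.11 (1 of 7, 1 adjusted over the list alone; adjusted p = 1.5e-05, adjusted p = 5.2e-05 with an estimated correlation). The 12 genes of antigen presentation were lower in basal ganglia with none called, H2-T23 at −0.48 ± 0.09 (adjusted p = 0.012, adjusted p = 0.035 with an estimated correlation). Of 13 glutathione transferases none was called in hippocampus, with Gstm6 at 0.86 ± 0.11 (adjusted p = 0.02, adjusted p = 0.32 with an estimated correlation). The 4 sex-linked genes were none of them called in hippocampus, with Eif2s3y at −0.68 ± 0.08 (adjusted p = 0.016, adjusted p = 0.16 with an estimated correlation). Astrocyte, endothelial and known strain-variant genes were called in no region as lists, with lowest adjusted p of 0.077, 0.17 and 0.37 (0.34, 0.48 and 0.47 with an estimated correlation).

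Strains were compared within each region with an F test over the strains (limma, adjusted p under 0.05). The named genes are given with the strains that carry them, such as Chil3, a chitinase-like protein, in C3H/HeJ and Pttg1, the separase inhibitor securin, in C57BL/6J. The test called 15544 probes in cerebellum (75.1% of those tested), 13280 in olfactory bulb (64.2%), 12520 in frontal cortex (60.5%), 8750 in cingulate cortex (42.3%), 7718 in amygdala (37.3%), 7279 in hippocampus (35.2%) and 6412 in basal ganglia (31%). In all 19335 probes were called in at least 1 region and 1911 in every region. Strains were scanned mostly on separate days, 43 of 68 scan days holding 1 strain, and with scan day as a block 1032 probes were called, 1032 of them in olfactory bulb and at most 1 in any other region where the block could be estimated. Leaving out replicate 1, 2 or 3 of every group gave 9972 to 10411 in cerebellum, 4368 to 9077 in olfactory bulb and 4559 to 7018 in frontal cortex. It gave 1241 to 9580 in cingulate cortex, 1780 to 3910 in amygdala, 1406 to 2208 in hippocampus and 1427 to 5595 in basal ganglia, so the order of the regions was not stable. The highest counts over all alternatives lay between 16771 in olfactory bulb and 18619 in cingulate cortex. Within the arrays before the gap in scanning 11169 were called and after it 15304, each with fewer strains. Because most scan days held 1 strain, day and strain are largely confounded in these counts.

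Single strains carried large differences in a few genes. Chil3, made by macrophages, was 4.32 ± 0.18 higher in C3H/HeJ than in the other strains (6 of 6 regions, limma adjusted p = 5.7e-56), and Pttg1 was 2.39 ± 0.14 higher in C57BL/6J (7 of 7, 5.4e-35). Crym, the thyroid hormone binding protein that marked hippocampus, was lower in NOD/LtJ at −3.88 ± 0.16 in 7 of 7 regions (6.8e-52). Me1, the cytosolic malic enzyme, was lower in SPRET/Ei at −4.07 ± 0.12 in 6 of 6 regions (1.1e-77), where Cwc22, a splicing factor, was higher by 3.96 ± 0.07 in 7 of 7 (1.6e-122). Amigo3, a membrane protein of the leucine-rich repeat family, was higher in MOLF/Ei by 3.47 ± 0.05 in 7 of 7 (4.6e-173). Il13ra2, a decoy receptor of interleukin 13, was the lowest gene of 3 wild-derived strains, at −3.93 ± 0.40 in CAST/Ei (6 of 6), −3.85 ± 0.53 in MOLF/Ei (5 of 5) and −3.76 ± 0.37 in PWD (7 of 7), with adjusted p of 2.9e-15, 1.2e-09 and 1.8e-16. Nup210l, a nucleoporin, was lower in DBA/2J at −3.82 ± 0.27 in 7 of 7 regions (3.1e-30). Whether sequence differences under the probes lowered Il13ra2 or Me1 in the wild-derived strains was not tested.

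Several genes took different levels in many strains. Pdxdc1, a decarboxylase-like protein, was higher in BALB/cByJ (2.45 ± 0.18, 7 of 7 regions, limma adjusted p = 3.1e-27) and PERA/EiJ (2.64 ± 0.20, 7 of 7, 1.8e-26), against other strains with 196 of 336 and 198 of 338 arrays well above background. It was lower in SJL/J (−2.93 ± 0.18), BTBR (−2.74 ± 0.18) and PL/J (−2.46 ± 0.19), each in 7 of 7 regions, where its spot was well above background on 11 of 20, 5 of 19 and 4 of 17 arrays. These falls (adjusted p = 2.8e-37, 1.2e-32 and 1e-25) are therefore measured near background. Naip6, an intracellular sensor of bacteria, was higher in CAST/Ei (3.08 ± 0.19, 7 of 7, 1.4e-41) and lower in the strain whose label ends in SvlmJ (−1.88 ± 0.18), C3H/HeJ (−1.71 ± 0.17) and FVB/NJ (−1.67 ± 0.18), each in 7 of 7 regions. Among the arrays before the scan gap, which leave out the wild-derived strains, these 3 differences were −0.45, −0.41 and −0.24 and no longer called. Over all strains 4 of 22 named differences lost their call before the gap and 1 of 20 after it. With the deposited ratios 2 of 42 lost it, and with flagged spots kept 2 of 42. Mela, an antigen first found in melanoma, was higher in AKR/J (3.15 ± 0.25), C58/J (2.68 ± 0.20) and DBA/2J (1.93 ± 0.37), in 7, 7 and 4 of the regions with a value, which numbered 7, 7 and 4 (9.6e-25, 2.6e-26 and 6.4e-06).

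Other strains had leading genes of their own. Serpina3n, a serine protease inhibitor of reactive astrocytes, was 2.34 ± 0.12 higher in the strain whose label ends in SvlmJ and Kiss1, the kisspeptin precursor, 2.13 ± 0.23 higher in BTBR. Rab36, a small GTPase, was 2.01 ± 0.20 higher in FVB/NJ. Cilk1, a kinase of cilia, was 2.13 ± 0.08 higher in SJL/J, Zfp874a, a zinc finger protein, 1.73 ± 0.07 higher in C57L/J (well above background on 167 of 401 arrays of the other strains) and Ccr10, a chemokine receptor, 2.69 ± 0.20 higher in PWD. Lower genes were Htr3a, a serotonin-gated channel, in A/J (−2.27 ± 0.24), Stk25, a kinase, in C57L/J (−2.40 ± 0.09) and Cap1, an actin regulator, in C57BL/6J (−2.37 ± 0.32) and AKR/J (−1.87 ± 0.30, 6 of 7 regions). Others were Arl2bp in BALB/cByJ (−1.51 ± 0.08), Kcnh1, a potassium channel, in PERA/EiJ (−1.49 ± 0.22) and Dmac2l in SWR/J (−2.08 ± 0.07). Apart from Cap1 in AKR/J, each of these went the same way in every region with a value, and the adjusted p-values from limma were 1e-06 or lower. The leading genes of NOD/LtJ, NZB/B1NJ and SWR/J among those that were higher were the same, S100a11, a calcium-binding protein, at 2.07 ± 0.23, 2.21 ± 0.23 and 2.5 ± 0.22. In the Cy3 channel alone, which holds the brain RNA, S100a11 differed by 0.43, −0.03 and 0.71 and was not called. For Serpina3n and Cilk1 the Cy3 channel gave 1.33 and 1.42, and for Arl2bp −1.05, still called. It also gave 0.17 for Kcnj12 in A/J (ratio 1.75 ± 0.62), 0.53 for Fabp6 in C58/J (ratio −1.88 ± 0.38, well above background on 125 of 200 arrays of the other strains) and 1.80 for Trim15 in NZB/B1NJ (ratio −2.52 ± 0.19).

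Counted over all strains, 2107 probes were called in at least 1 strain (limma, adjusted p under 0.05 and at least 2-fold against the mean of the other strains), 1347 of them in 1 strain only. SPRET/Ei had 606 (288 higher, 318 lower), NZB/B1NJ 549 (324 and 225), PWD 315, CAST/Ei 300, SWR/J 288, MOLF/Ei 245, A/J 204 (24 and 180) and DBA/2J 202 (29 and 173). The fewest were 23 in FVB/NJ, 28 in C57BL/6J, 35 in C57L/J and 44 in C3H/HeJ, and the median was 300 over the wild-derived and 80.5 over the classical strains. In NOD/LtJ, NZB/B1NJ and SWR/J the Cy5 channel, which by its label held the same reference RNA on every array, carried a median of 76.6% of the ratio difference over 1026 calls, against 35.2% in the other 13 classical and 12.9% in the wild-derived strains. By strain it was 94.6% in NZB/B1NJ, 56.9% in A/J, 52.6% in NOD/LtJ, 52.2% in SWR/J and 46.6% in SJL/J and in DBA/2J. Within the arrays before the scan gap 530 probes were called, within those after it 1630, and with means per strain and scan day 2246. Each period compared fewer strains, and the wild-derived strains all lay after the gap, so its count is not of the same strains as 2107. The labels do not say whether arrays of different regions of a strain share pools of animals, and if they do these p-values are too small.

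**Figure D3:**
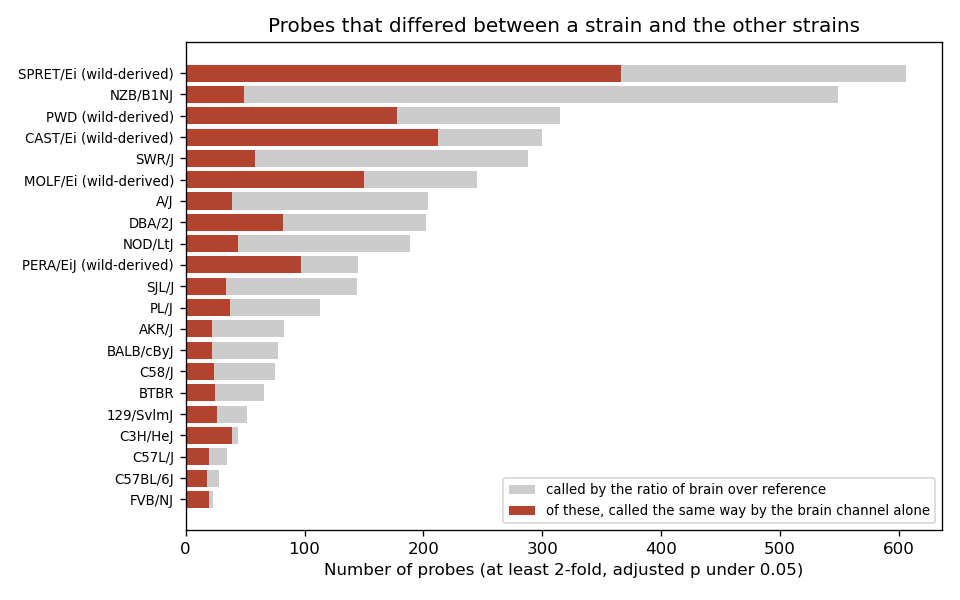
Number of probes called in each strain against the mean of the other strains by the ratio of brain over reference (grey), and the part of them that the brain channel alone called the same way (red; limma, adjusted p under 0.05 and at least 2-fold). SPRET/Ei has 606 calls, of which 366 were also called in Cy3, and NZB/B1NJ has 549, of which 49 were.

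Wild-derived strains were compared with classical strains to ask which genes follow the origin of a strain. Pdxdc1 was higher in the wild-derived strains by 2.94 ± 0.66 and Naip6 by 2.60 ± 0.53, both in 5 of 5 strains (limma adjusted p = 0.0095 and 0.0052), the spot of Pdxdc1 being well above background on 141 of 281 arrays of the classical strains. Lrrc18, a leucine-rich repeat protein, was higher by 2.16 ± 0.21 (4.1e-06), Ccr10 by 2.10 ± 0.46 (limma adjusted p = 0.0083) and Stk25 by 2.04 ± 0.50 (limma adjusted p = 0.017), each in 5 of 5. Lower were Tlx1, a homeobox factor, at −1.63 ± 0.25 in 4 of 5 strains, and Olfr1042, an olfactory receptor, at −1.44 ± 0.28 in 4 of 5 (well above background on 54 of 86 arrays). So were Dync1li1, a dynein subunit, at −1.39 ± 0.18 in 5 of 5, Nlgn3, a neuroligin of synapses, at −1.33 ± 0.27 in 5 of 5, and Camkk2, a calcium-activated kinase, at −1.28 ± 0.24 in 4 of 5. Counts such as 5 of 5 are against the mean of the classical strains, and single strains overlapped. Against the mean of all strains Pdxdc1 stood at 2.30 in BALB/cByJ, 2.27 in C3H/HeJ and 1.77 in DBA/2J, beside 2.10 to 2.48 in the wild-derived strains, and Naip6 at 1.36 in SWR/J beside 1.33 in SPRET/Ei. Stk25 was at 1.73 in PL/J, and Ccr10 at 1.35 in SJL/J against 0.17 in SPRET/Ei. PERA/EiJ lay within the classical range for Dync1li1 (0.22) and Nlgn3 (−0.15). The adjusted p-values of the 5 lower genes in limma were 0.00039, 0.0036, 9e-05, 0.0048 and 0.0024. In all 75 probes were higher and 27 lower, 102 together, with strain means as replicates. All 5 wild-derived strains were scanned after the gap, and against the 5 classical strains scanned there 10 probes were called. Pdxdc1 kept its call there and the other 9 named genes lost it, with values such as 1.81 for Lrrc18, −1.44 for Dync1li1, 0.95 for Naip6 and −0.69 for Nlgn3. Camera called 6 of the 27 lists higher in the wild-derived strains, namely striatal projection neurons (adjusted p = 0.0022), GABA-A receptor subunits, immediate early genes and neuropeptides (0.034 each), and Purkinje cells and amygdala neurons (0.047 each). All 6 had adjusted p = 0.45 with an estimated correlation, and none of their genes was called, adjusted over the list alone or over all genes.

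DBA/2J and C57BL/6J, the parents of a widely used panel of recombinant inbred lines, differed in a few genes in 6 of the regions. Tmem87a, a membrane protein of the Golgi, was higher in DBA/2J by a mean of 2.33 ± 0.12 over the regions (1.37 to 2.80) and Lrp6, a Wnt co-receptor, by 1.39 ± 0.10 (0.67 to 1.67). Zfp874a (−1.74 ± 0.10, from −2.31 to −1.08), Nudt19, a hydrolase of coenzyme A (−1.35 ± 0.09, from −2.05 to −0.02) and Trim6 (−1.17 ± 0.10, from −1.47 to −0.88) were lower. These 5 genes were called in 6 of 7 regions and were chosen after their values were seen, since 1 probe, without a gene name, was called the same way in all 7. Of the genes known to vary between the strains, Glo1, glyoxalase 1, differed by 0.85 ± 0.29 (−0.48 to 1.94, called in 2 regions) and Alad, an enzyme of haem synthesis, by 1.26 ± 0.19 (0.92 to 1.53, 1 region). Kcnj9, a potassium channel, differed by 1.13 ± 0.19 (0.49 to 1.85, 1 region) and Entpd4, a nucleotide hydrolase, by −1.02 ± 0.12 (−1.52 to −0.50, 3 regions). Gabra2 (0.74 ± 0.16) and Tyr (−0.05) were called in 0 regions. The standard errors of these means take the regions as independent. The labels do not say whether regions share pools of animals, and if they do the standard errors are too small.

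The number of probes that differed between DBA/2J and C57BL/6J depended on single arrays. Calls numbered 673 in cerebellum (336 higher in DBA/2J, 337 lower), 345 in amygdala (110 and 235), 266 in frontal cortex (84 and 182), and 202 in olfactory bulb (35 and 167). There were 67 in cingulate cortex (35 and 32), 48 in basal ganglia (21 and 27) and 33 in hippocampus (7 and 26). In all 1331 probes were called in at least 1 region (limma, adjusted p under 0.05 and at least 2-fold). Over all alternatives the counts ran from 65 to 1831 in cerebellum, 2 to 1857 in amygdala and 81 to 990 in frontal cortex. They ran from 32 to 620 in olfactory bulb, 6 to 445 in cingulate cortex, 13 to 310 in basal ganglia and 3 to 313 in hippocampus. In cerebellum the count was 157 without C57BL/6J replicate 2, 1182 and 1305 without C57BL/6J replicates 1 and 3, and 399 and 409 without DBA/2J replicates 2 and 3. In amygdala it was 35 without C57BL/6J replicate 1, 1043 and 2114 without its replicates 2 and 3, and 131 without DBA/2J replicate 1. In cingulate cortex it was 18 without DBA/2J replicate 1 and 26 and 43 without C57BL/6J replicates 1 and 2, and in hippocampus 14 without DBA/2J replicate 2 and 12 without C57BL/6J replicate 2. In basal ganglia it was 158 without C57BL/6J replicate 1 and 22 without DBA/2J replicate 3, in olfactory bulb 85 and 124 without C57BL/6J replicates 2 and 3 and 103 without DBA/2J replicate 2, and in frontal cortex 169 without DBA/2J replicate 2. C57BL/6J cerebellum replicate 2 correlated poorly with its group (median r = 0.34) and C57BL/6J amygdala replicate 1 was closest to the profile of another region, and without the 5 arrays with such doubts 566 probes were called. With scan day as a block, which could be estimated in amygdala, 2 probes were called.

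Among other strains the known variable genes were called as follows. Glo1 was higher in BALB/cByJ (1.27 ± 0.15) and MOLF/Ei (1.68 ± 0.23) than in the other strains (limma adjusted p = 2.1e-12 and 3.5e-10). Alad was lower in PWD (−1.16 ± 0.14) and SPRET/Ei (−1.03 ± 0.12) and in the wild-derived strains as a class (−1.02 ± 0.20), with adjusted p = 5.3e-13, 1.7e-13 and 0.0043. Kcnj9 was lower in NZB/B1NJ (−1.05 ± 0.14, 9.7e-11). In that strain the Cy3 channel alone called 49 of 549 ratio calls the same way, and its value for Kcnj9 is not given here. Gabra2, Entpd4, Ide, Hc and Tyr were called in no strain against the others, and Apoa2 in none of those where it had enough values.

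Some strain differences were confined to few regions, which the test of strain by region interaction addressed. Lefty1, an inhibitor of Nodal signalling, was 1.81 higher in hippocampus of the strain whose label ends in SvlmJ than in that of the other strains and 0.06 to 0.29 higher in its other regions (F = 11.1, limma adjusted p = 7.8e-53). Col9a1, a cartilage collagen, was 2.89 higher in cerebellum of CAST/Ei against 0.07 to 0.48 elsewhere (F = 7.99, 1.5e-40), and Comp, a cartilage matrix protein, 1.93 higher in cerebellum of SPRET/Ei against −0.06 to 0.26 (F = 6.8, 4.2e-36). Klk1b27, a kallikrein, was 3.06 higher in olfactory bulb of C3H/HeJ against 0.55 to 2.76 (F = 7.4, 1.1e-39), and Onecut2, a transcription factor, 2.57 higher in cerebellum of SPRET/Ei against 0.11 to 1.52 (F = 5.88, 2e-30). The first 2 of these and Klk1b27 rest on 2 arrays with a value each. In all 1344 probes (6.49%) were called, 541 within the arrays before the scan gap, 697 after it and 3786 with scan day as a block. With the residuals of a fit without interaction moved at random between arrays, up to 1010 were called. Without replicate 1, 2 or 3 of every group 271, 404 and 1041 were called, and with array weights 16152. Over 19879 probes strain took a median of 27.6% of the variance (quartiles 20.4 and 36.5) and region 11.7% (5.71 and 22.3). Their interaction took 20.4% and differences between arrays of a group 33.5%, and region exceeded strain in 4640 probes. These are raw shares of the sums of squares, not adjusted for the number of terms. Strain has more terms than region and the interaction more than both, and noise alone raises a share with its terms. The strain share also holds differences between scan days.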

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

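The test of the reference channel, that of the brain channel, the contrast of region profiles for the AKR/J array and the share of lower calls were chosen after the result was seen. In groups of 4 arrays, a value far from the other 3 was marked by a test of gaps within the group, which marks about 1 in 20 groups by chance. Of 20 such tests in 5 groups, 6 stood apart. C57BL/6J cerebellum replicate 2 had 66.2% of spots well above background in Cy3 (nearest other 94.3%), a correlation of 0.49 with the cerebellum profile (0.90) and a median correlation of 0.34 with its group (0.83). C3H/HeJ cerebellum replicate 3 had a median correlation of 0.75 with its group (0.91).

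AKR/J olfactory bulb replicate 2 had 92.8% of spots well above background (nearest other 95.4%) and a correlation of −0.18 with the olfactory bulb profile (0.83). Its correlation with the frontal cortex profile was higher by 0.89, which is consistent with a wrong region label. The median of 9 bulb markers differed from the AKR/J frontal cortex arrays by −0.05, against 3.03 in the other 3 bulb arrays, with S100a5 at −0.16 (5.07 in the other bulb arrays) and Cdhr1 at 0.50 (5.31), so a dissection that mixed frontal cortex into bulb is not what the markers show. Its best correlation with a region profile was not among the lowest, since 18.3% of arrays had a lower one, and 14.7% had a lower share of spots well above background. A failed hybridisation was thus not marked, while a poorer one stays possible. By the labels AKR/J frontal cortex has 2 arrays, while most groups have 3.

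In NOD/LtJ, NZB/B1NJ and SWR/J the Cy5 channel, by its label the same RNA on every array, carried a median of 76.6% of the ratio difference (52.6%, 94.6% and 52.2% by strain, and 56.9% in A/J), and the Cy3 channel alone called 14.7% of the 1026 calls the same way (23.3%, 8.93% and 20.1% by strain, and 19.1% in A/J), against 35.2% and 35.6% in the other 13 classical strains. Over all probes the ratio differences of NOD/LtJ, NZB/B1NJ and SWR/J correlated with the Cy3 differences at −0.012, −0.088 and 0.1. With the Cy5 differences they correlated at −0.64, −0.7 and −0.57, and Cy5 alone called 1199, 2553 and 1308 probes. Cy3 alone called 450, 804 and 536 probes. The ratio differences of these strains thus went with the Cy5 channel more than with Cy3, though single genes may still differ in brain. An effect shared by both channels would cancel in the ratio and not in Cy3 alone. The share of Cy5 and the low agreement with Cy3 therefore do not settle how far brain expression differed. A change in the lot of the reference RNA is not given in the sources used here, so the source of the Cy5 difference stays open. Similarity of strain profiles fell with the gap between median scan days (Pearson r = −0.516, permutation p = 2e-05, adjusted p = 2.5e-05, rho = −0.509, 21 strains, 5 relations tested, and r = −0.589 without the 2 strains farthest in time), where 1e-05 is the smallest p the permutations can give. Among the 16 classical strains alone the correlation was −0.589 (permutation p = 2e-05), and in their Cy3 channel −0.627 (permutation p = 3e-05). Scan time also went with similarity in the Cy3 channel alone over all strains (r = −0.557, permutation p = 1e-05), so a batch effect may reach both channels. Ancestry stays open, as C57BL/6J (rank 4, behind NZB/B1NJ, SWR/J and NOD/LtJ) and C57L/J (rank 10) had a mean rank of 7 among the 20 partners of C58/J, and CAST/Ei, MOLF/Ei, PWD and SPRET/Ei were each closest to another wild-derived strain while PERA/EiJ was closest to SWR/J.

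Lower calls in wild-derived strains could come from sequence differences under the probes. The highest share of lower calls among CAST/Ei, MOLF/Ei and PWD was 37.1%, so higher calls prevailed and mismatches do not account for most calls of these strains. This share does not tell whether the lower calls came from mismatches. In SPRET/Ei lower calls were 52.5%, and they varied less between regions than higher calls did, by −0.031 in median SD (0.270 over 247 probes against 0.301 over 239, permutation p = 0.0093). No other strain was tested in this way, and the permutation took probes as independent. The difference therefore does not tell mismatches from lower expression. The share of lower calls by itself does not single out SPRET/Ei, since it ran from 28.2% in BALB/cByJ to 88.2% in A/J among the classical strains. The sequences of the strains were not used here.

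Genes whose strain difference changed with region were marked by a difference between groups, Lefty1 (F = 11.1), Col9a1 (7.99), Klk1b27 (7.4), Comp (6.8) and Onecut2 (5.88) among 1344 probes. Of 100 splits of the samples 1, the real one, gave as many (highest other 1010). The whole count was thus larger than in the other splits. A split alone still gave up to 1010 calls, so single calls can be due to chance. The real grouping also gave the largest count for each region against the others (1 of 100 splits, 1223 against 42) and cingulate against frontal cortex (1 of 100, 37 against 1). It did so for strains within regions (1 of 100, 19335 against 2734), each strain (1 of 100, 2107 against 138) and the strain classes (1 of 100, 102 against 28). For lists by region it did too (1 of 40, 76 against 44), where single list calls can likewise be due to chance. The split that set the 5 classical strains scanned after the gap against the others called 55 probes. Chance was not excluded for lists by strain class (17 of 100 splits, 6 against 11) or for DBA/2J against C57BL/6J (27 of 100, 1331 against 2401). The splits did not keep scan days together, so a count above the splits does not separate strain from scan day. An effect of scan day stays open, and strains within regions gave 1032 with scan day as a block.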

How the results depend on the processing

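The alternatives chosen after seeing the data were those on flagged spots, the Cy3 channel, doubted arrays, the scan gap, PERA/EiJ, means per strain and scan day, and the scan day of regions. The count over regions stayed within 1.5-fold in 17 of 18 alternatives (1124 to 1953) and that of cerebellum in 18 of 18 (756 to 1194), among them Aquantile, which leaves ratios as they are and could change no count. With the scanner software's processed signals the counts were 1953 for regions, 221 for amygdala, 439 for basal ganglia, 131 for cingulate cortex, 149 for frontal cortex, 419 for hippocampus, 372 for olfactory bulb, 72 for cingulate against frontal cortex, 3220 for DBA/2J against C57BL/6J, 5411 for each strain and 281 for the strain classes. The deposited table gave 82 for cingulate cortex and the Cy3 channel alone 298 for hippocampus. The interaction stayed so in 8 of 18, with 2637 in the deposited table, 2566 with median centring, 550 without wild-derived strains, 16152 with array weights, 3786 with scan day as a block, 2619 with flagged spots kept, 541 before and 697 after the scan gap, 271 to 1041 without replicate 1, 2 or 3, and 1547 without the fourth arrays of the few groups that have them. Strains within regions fell to 1032 with scan day as a block and to 11169 before the gap. Each strain gave 530 before the gap, where fewer strains were compared and no wild-derived one. The strain classes gave 10 among strains after the gap, with fewer strains, and 167 without PERA/EiJ. DBA/2J against C57BL/6J gave 2 with scan day as a block, 566 without doubted arrays, and 601 to 2660 without replicate 1, 2 or 3. In the Cy3 channel alone Fabp6 in C58/J (0.53), S100a11 in NZB/B1NJ (−0.03) and Trim15 in NZB/B1NJ (1.80) were reversed. Unless stated, the cause was not tested. Scan day as a fixed block could not be estimated for each strain against the others. No paired analysis was possible because the replicate numbers follow the order of deposit. The signal over background limits the precision of the dimmest arrays.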

Other observations

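No test in this part was chosen after its result was seen. Some subunits of transmitter receptors differed between regions. In cerebellum Gabrd, the extrasynaptic GABA-A receptor subunit, was higher by 1.38 ± 0.10 beside Gabra6, while Gabra4 (−1.84 ± 0.14) and Gabra3 (−1.14 ± 0.08) were lower. In basal ganglia Gabra4 (1.54 ± 0.15) and Gabrd (1.05 ± 0.10) were higher, and in amygdala Gabrg1 (1.64 ± 0.10) was higher and Gabrd (−1.09 ± 0.10) lower. In hippocampus Gabra6 stood at −1.08 ± 0.10 against a mean of regions that includes cerebellum, where it was high. This value therefore does not show a fall particular to hippocampus. The list of 13 GABA-A subunits was called in amygdala in limma's camera (adjusted p = 0.017, adjusted p = 0.26 with an estimated correlation). In cerebellum its median was −0.42, its mean 0.10 and the test downward without a call (adjusted p = 0.59, adjusted p = 0.83 with an estimated correlation).

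Among glutamate receptor subunits, cerebellum had higher Grin2c (1.42 ± 0.06), the NMDA receptor subunit of mature granule cells, and Gria4 (1.25 ± 0.09), and lower Grik5 (−1.73 ± 0.05), while hippocampus had higher Grik4 (1.36 ± 0.07), a kainate receptor subunit. The list was called in no region (lowest adjusted p = 0.19 in camera, adjusted p = 0.33 with an estimated correlation). Of 18 monoamine receptors Htr2a, a serotonin receptor, was higher in cerebellum (1.44 ± 0.16) and lower in amygdala (−1.06 ± 0.16). The list was lower in hippocampus without a called gene (adjusted p = 0.00039, adjusted p = 0.16 with an estimated correlation). In basal ganglia, where Drd2 led, the list was called with a median of 0.00 (adjusted p = 0.019, adjusted p = 0.38 with an estimated correlation). In wild-derived against classical strains Htr3a, at 1.68 ± 0.54, was called adjusted over the list alone and not over all genes.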
